A study of Mus musculus with 2 samples.

How the data were processed

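Total RNA was measured by RNA-seq in 2 forebrains of mouse embryos at embryonic day 14.5, grouped by the labels as 1 group of 2 biological replicates. Per the labels' protocols, RNA was extracted with the Ambion mirVana method, RNA longer than 200 nt was used with 10 ng per library, spike-in RNAs were added, and a general protocol named after Smart-seq, a method that primes on poly(A) tails, was linked although the molecule was called total RNA. For each library there was a table of genes and a table of transcripts. Reads were assigned to assembly mm10 (GRCm38) with GENCODE release M4, per the files' notes. The aligner, the quantification program, their versions and whether counting used the strand were not given in the sources used here, so reads of overlapping genes on opposite strands may not be told apart.

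Per the file headers, the deposited values were expected counts, TPM, FPKM and the percent of a gene's TPM held by each transcript. The expected counts are estimated read numbers that need not be whole. TPM are transcript levels that the authors scaled to a constant sum over all rows of a library, spike-ins and short RNA models included, and FPKM were deposited beside them. The deposited tables also held posterior mean counts and TPM, and an interval for each TPM whose level the files do not state. These intervals are centred on the posterior mean and not on the TPM, which lay outside its interval for 1202 genes in replicate 1 and 1545 in replicate 2. Each effective length was 99 nt under the length, as for 100-nt reads of a single end, so TPM of genes barely longer than a read rest on very short effective lengths and are unreliable. The gene tables held 69691 rows, of which 43346 were Ensembl genes, 26248 had numeric IDs and 97 were control sequences (96 spike-ins and a phage genome). Gene names, types and coordinates came from GENCODE release M21 on the same assembly, by ID without version, which matched 42462 of the 43346 genes (98.0%) and 101510 of 103639 transcripts. Ahsp, Rmst and Sox2ot, each a member of a gene list, were not matched and were not analysed here.

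The depth was 35310017 and 29250404 expected counts. A count of 0 allows up to 3 counts, which for a transcript with an effective length of 1 kb was 0.131 TPM in replicate 1 and 0.170 TPM in replicate 2. Shares of counts carry 95% Wilson binomial intervals. Means and SDs are over the 2 libraries.

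The design has 1 group, so no test between groups was made, and an exact test on 2 libraries cannot go below p = 0.5. Instead, 32 gene lists, 33 gene pairs, 20 genes for transcript shares and the rule for the genes named were fixed before the data were examined, together with the alternatives unless said otherwise. Genes named were up to 5 members of each list with the highest mean TPM, members of lists of other tissues with a mean TPM under 0.1, genes of the pairs, the 15 nuclear protein-coding genes with the highest mean TPM, the 10 genes with the largest log2 ratio in each direction among those that differed, and the genes for transcript shares. Xist and the other sex-linked genes were fixed too, as values. Outside the rule, Cux2, Dlx1as, Gm37376, H1f0, Hist1h1t and Hist1h2ap, and Col1a1 and Malat1 among the differing genes, were chosen after their values were seen. Some members of the lists, pairs and transcript sets are not reported here, but all counts and medians include them.

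A list's level was the median over members of the mean log2(TPM + 1), ranked among 10000 random lists of as many nuclear protein-coding genes. It was called high from the 97.5th percentile and low to the 2.5th. A list's difference was its median log2 ratio of TPM + 1, replicate 2 over replicate 1, ranked among 10000 random lists matched on expression in 20 bins. Such ranks describe these libraries, as genes are not replicates. Genes differed between the embryos when the mean TPM was 5 or more, the ratio 2-fold or more and the deposited TPM intervals did not overlap. Pairs were compared as log2 ratios of TPM within each library with no pseudocount and called when the intervals lay apart in both libraries in the same direction. In a ratio, a gene under 3 counts was set to the level of 3 counts. The spread between libraries was estimated with edgeR (common dispersion, TMM normalization, default expression filter) on expected counts rounded to whole numbers, and the chi-square of the counts covered genes with 10 or more counts in all. Histone genes were taken by symbol.

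The steps were tested on simulated data. For the spread between the 2 libraries, simulated coefficients of variation of 0.1, 0.2 and 0.4 came back as 0.100, 0.200 and 0.390 over 16379, 16256 and 16004 genes. For genes that differ between the 2 embryos, with 10957 genes eligible and counting noise alone, 100 of 100 genes simulated at 2.5-fold, 49 of 50 at 4-fold and 40 of 50 at 0.25-fold were called, where the lowered genes can fall under the mean TPM required, and 0 of 10757 unchanged genes were. This run used exact Poisson intervals of the simulated counts and not the deposited TPM intervals. It had no noise beyond counting, so it does not give the rate of false calls in the real libraries. For the list difference over 22678 genes, 10 of 10 lists raised 1.3-fold and 0 of 20 unchanged lists were called. Here each gene was drawn independently with 1 common spread and no trend with length or GC content. These runs therefore do not give the rate of false calls for lists whose members vary together. The alternatives were other thresholds, pseudocounts, backgrounds and units, TMM or DESeq2 scaling, posterior means, protein-coding transcripts only and each library alone. Added after seeing the data were list ranks on residuals of a spline fit on transcript length, GC content and expression and ranks matched on effective length as well, and histone medians without H1f0 and without pseudogenes. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.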

Results

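The series measured total RNA of the mouse forebrain at embryonic day 14.5, a stage at which progenitors of the cerebral wall divide while neurons of the cortex and striatum form. The labels give 2 samples in 1 group, called E14.5 forebrain here, and number them as biological replicates 1 and 2. Each sample is described as the forebrain of a single embryo of strain B6NCrl, a C57BL/6 substrain, and the embryos came from different donors collected on different days. Each library was made from 10 ng of RNA longer than 200 nt, with synthetic spike-in RNAs added. The summed expected counts were 35310017 in replicate 1 and 29250404 in replicate 2. The design has no second group, so the comparisons were those between genes and gene groups within the libraries and those between the 2 embryos. Errors are standard deviations of the 2 libraries (n = 2).

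The most abundant nuclear protein-coding gene was Tuba1a. This alpha-tubulin of newborn neurons (ENSMUSG00000072235.5, chromosome 15, 98949837 to 98953703, minus strand, GRCm38) stood at 16994 ± 207 TPM (SD, n = 2). Actb, cytoplasmic beta-actin, followed at 8596 ± 40.0 TPM and Stmn1, a regulator of microtubules, at 6653 ± 441 TPM. The next of the 15 most abundant nuclear protein-coding genes were the actin-binding thymosin gene Tmsb4x at 6042 ± 143 TPM and the imprinted gene Nnat at 5758 ± 205 TPM. The alpha-globin gene Hba-a2 stood at 5686 ± 852 TPM and Ftl1, the ferritin light chain, at 5498 ± 240 TPM. The other 8 were Ubb, Tmsb10, Eef1a1, H3f3a, Ppia, Actg1, Cfl1 and Hbb-bs, between 4462 ± 82.5 and 2821 ± 639 TPM. These 15 genes held 8.43% of all TPM in replicate 1 and 8.65% in replicate 2. In all, 14213 genes had a TPM of 1 or more in both libraries, among them 12808 of the 21474 protein-coding genes and 214 lincRNA genes.

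The question of which cell types and regions the tissue holds was addressed with 32 gene lists. Of these, 9 ranked high among random lists of nuclear protein-coding genes, and 1 ranked low. Neuronal genes had a median of 231 ± 19.4 TPM over 12 genes (100th percentile). Within it, Tubb3, the neuronal beta-tubulin, stood at 1576 ± 128 TPM, the growth cone gene Gap43 at 760 ± 99.1 TPM, Stmn2 at 601 ± 100 TPM, the tau gene Mapt at 393 ± 154 TPM and Map2 at 284 ± 54.4 TPM. Cell cycle genes had a median of 97.0 ± 11.3 TPM over 12 genes (100th percentile), with Cdk1 at 214 ± 52.3 TPM, the replication clamp Pcna at 199 ± 20.8 TPM, Ccnb1 at 159 ± 28.0 TPM, Top2a at 119 ± 7.12 TPM and Rrm2 at 116 ± 3.65 TPM. All 12 radial glia genes were detected, with a median of 36.1 ± 2.24 TPM (99.3th percentile), led by the fatty acid binding protein gene Fabp7 at 1300 ± 51.3 TPM and Vim, vimentin, at 559 ± 58.9 TPM. Slc1a3, Lhx2 and the Notch target Hes5 followed at 96.6 ± 17.0, 78.6 ± 8.34 and 66.8 ± 6.59 TPM. Intermediate progenitor genes had a median of 41.9 ± 1.23 TPM over 9 genes (98.7th percentile), with Hes6 at 192 ± 10.4 TPM, Gadd45g at 103 ± 9.68 TPM, the proneural factor Neurog2 at 71.2 ± 3.57 TPM, Btg2 at 63.0 ± 7.98 TPM and Mfng at 41.9 ± 1.23 TPM. Dorsal telencephalic genes had a median of 39.4 ± 1.2 TPM over 9 genes (98.7th percentile). The bHLH factors Neurod6 and Neurod2 led them at 384 ± 17.4 and 65.4 ± 17.1 TPM, before Fezf2 at 59.5 ± 7.57, Emx1 at 54.6 ± 3.45 and Tbr1 at 39.4 ± 1.2 TPM. Against random lists drawn only from protein-coding genes with a mean TPM of 0.1 or more, the radial glia, intermediate progenitor and dorsal lists fell to the 95.8th, 95.3th and 94.9th percentiles and were no longer high.

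**Figure D1:**
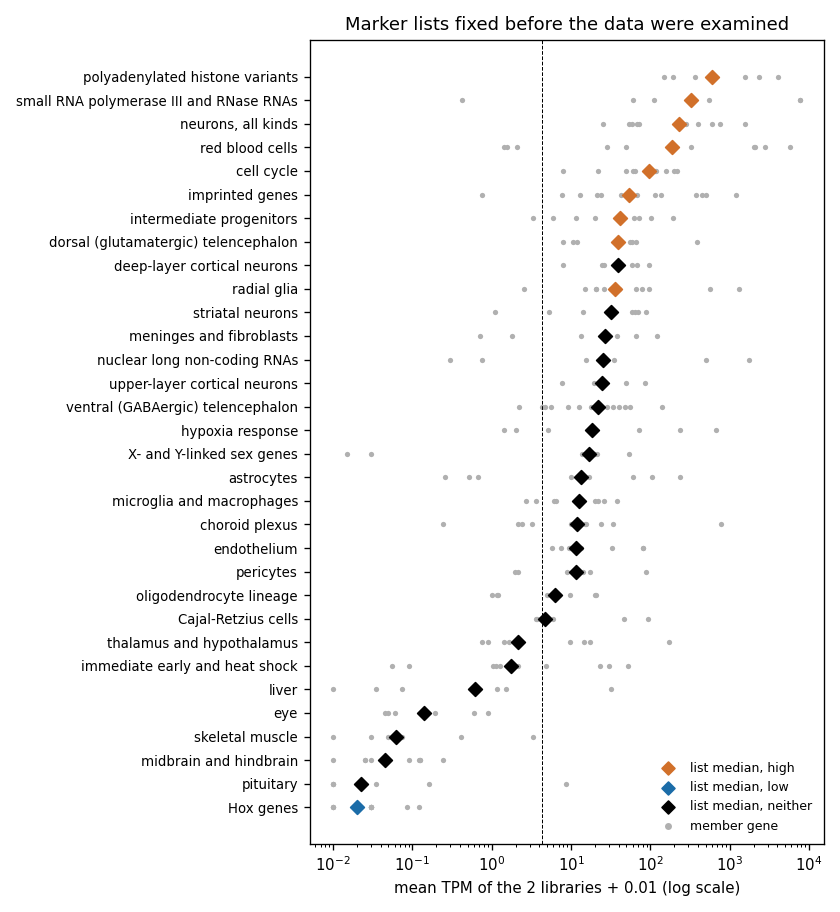
Each row is a gene list, each grey point the mean TPM of the 2 libraries of a member gene, and each diamond the mean of the 2 libraries' list medians, with 0.01 added for the log axis. Coloured diamonds mark lists called high (9) or low (1, the Hox genes), and the dashed line is the median of all 21460 nuclear protein-coding genes, 4.25 TPM.

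The deep-layer, upper-layer, ventral, striatal, Cajal-Retzius and thalamic and hypothalamic lists were not called high. Deep-layer cortical genes had a median of 39.4 ± 1.2 TPM over 7 genes (97.3th percentile), with Sox5 at 96.4 ± 18.5 TPM and Bcl11b, which encodes CTIP2, at 67.5 ± 7.32 TPM. Upper-layer genes had a median of 24.7 ± 8.72 TPM over 7 genes (92.1th percentile), with Cux1 at 85.8 ± 16.4 and Mef2c at 48.8 ± 18.4 TPM. All 15 ventral telencephalic genes were detected, with a median of 21.7 ± 1.45 TPM (95.5th percentile). The homeobox genes Dlx1 and Dlx5 and the GABA-synthesising enzyme Gad1 led them at 139 ± 15.4, 55.8 ± 13.7 and 48.1 ± 14.3 TPM. Striatal genes had a median of 32.0 ± 6.02 TPM over 9 genes (97.2th percentile), with Meis2 at 89.3 ± 9.11, Isl1 at 70.8 ± 4.59, Foxp1 at 63.6 ± 16.8 and the substance P precursor Tac1 at 58.0 ± 11 TPM. This list was high with replicate 2 alone (97.7th percentile). Cajal-Retzius genes had a median of 4.64 ± 0.891 TPM over 7 genes (50.4th percentile), where Calb2 at 92.4 ± 21.6 TPM and Reln, reelin, at 47.2 ± 2.53 TPM stood far above the other members. Thalamic and hypothalamic genes had a median of 2.12 ± 0.0530 TPM over 10 genes (33.5th percentile), led by Tcf7l2 at 173 ± 18.4 TPM.

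Genes of the lists for blood, vessels, meninges and glia were also detected. Red blood cell genes were high, with a median of 190 ± 155 TPM over 10 genes (99.99th percentile), and the adult globins Hba-a2, Hbb-bs, Hba-a1 and Hbb-bt stood at 5686 ± 852, 2821 ± 639, 2059 ± 214 and 2025 ± 181 TPM. The alpha-globin and the beta-globin genes are near-identical copies, so the split of reads within each pair is uncertain. Endothelial genes had a median of 11.7 ± 0.795 TPM over 10 genes (81.9th percentile), with the glucose transporter gene Slc2a1 at 80.7 ± 4.66 TPM and the tight junction gene Cldn5 at 80.2 ± 5.03 TPM. Pericyte genes had a median of 11.5 ± 1.61 TPM over 6 genes (75.8th percentile), led by Vtn at 89.2 ± 20.9 TPM. Meningeal and fibroblast genes had a median of 27.0 ± 6.61 TPM over 8 genes (95.5th percentile), with the collagen gene Col3a1 at 120 ± 24.8 TPM and Dcn at 65.1 ± 11.4 TPM. Choroid plexus genes had a median of 12.1 ± 2.36 TPM over 11 genes (81.1th percentile), although Ttr, transthyretin, reached 771 ± 9.78 TPM. Microglial genes had a median of 12.5 ± 1.38 TPM over 10 genes (83.3th percentile), led by the complement genes C1qb at 38.3 ± 0.297 TPM and C1qa at 22.1 ± 2.65 TPM and by Tyrobp at 26.3 ± 0.629 TPM. Of 9 oligodendrocyte lineage genes, 6 had a TPM of 1 or more in both libraries. This list had a median of 6.36 ± 1.87 TPM (59.6th percentile), with Olig1 at 20.8 ± 8.13 TPM. Of 8 astrocyte genes, 5 had a TPM of 1 or more in both libraries. The astrocyte list had a median of 13.5 ± 2.45 TPM (81.0th percentile), carried by Apoe at 236 ± 29.5 TPM and the gap junction gene Gja1 at 104 ± 17.5 TPM.

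Lists of tissues outside the forebrain had medians under 1 TPM, but only the Hox list was called low. Hox genes, which pattern the hindbrain and spinal cord, were low, with a median of 0.01 ± 0.0141 TPM over 12 genes (1.17th percentile). No read was assigned to Hoxa3, Hoxa4 or Hoxb3 in either library, and 3 reads, the number a count of 0 allows, would correspond to 0.0851 and 0.111 TPM for Hoxa3. Midbrain and hindbrain genes had a median of 0.0350 ± 0.0212 TPM over 9 genes (6.67th percentile). Among them, En2 had 1 read in each library, En1 stood at 0.0200 ± 0.0283 TPM, Phox2a at 0.0150 ± 0.0212 TPM and Fev at 0.0800 ± 0.113 TPM. Pituitary genes had a median of 0.0125 ± 0.0177 TPM over 6 genes (2.56th percentile), with no read for Pou1f1, Gh and Prl in either library. The exception was Pomc, the pro-opiomelanocortin gene, at 8.59 ± 2.76 TPM. With replicate 2 alone the pituitary list was low as well (1.25th percentile). Skeletal muscle genes had a median of 0.0525 ± 0.0530 TPM over 6 genes (5.05th percentile), and eye genes one of 0.13 ± 0.134 TPM over 6 genes (7.54th percentile). Liver genes had a median of 0.610 ± 0.332 TPM over 6 genes (15.6th percentile), with the albumin gene Alb at 0.0250 ± 0.00707 TPM and the transferrin gene Trf at 32.2 ± 5.61 TPM. Limited to genes with a mean TPM of 0.1 or more as background, 8 lists were low instead of 1. This filter took unexpressed genes out of the background but not out of the lists, which lowers ranks by construction.

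Among the remaining lists, imprinted genes were high, with a median of 53.6 ± 2.17 TPM over 16 genes (99.97th percentile). Their 5 most abundant members were Ndn, necdin, at 1186 ± 7.98 TPM, the long non-coding RNA Meg3 at 508 ± 124 TPM, Snrpn at 445 ± 60.2 TPM, Mest at 380 ± 25.7 TPM and Cdkn1c at 137 ± 0.113 TPM. Polyadenylated histone variants had a median of 590 ± 125 TPM over 7 genes (100th percentile). Hypoxia response genes had a median of 18.4 ± 3.24 TPM over 8 genes (89.7th percentile), with the glycolytic genes Ldha and Pgk1 at 670 ± 76.0 and 240 ± 21 TPM. Immediate early and heat shock genes had a median of 1.73 ± 0.898 TPM over 10 genes (27.8th percentile), with Dusp1 at 52.3 ± 3.56 TPM and Jun at 30.5 ± 0.785 TPM. Nuclear long non-coding RNAs had a median of 25.2 ± 10.8 TPM over 6 genes (90.5th percentile), led by Malat1 at 1775 ± 866 TPM. The 6 sex-linked genes had a median of 17.0 ± 2.0 TPM (85.1th percentile). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 1717, 1697, 1576 and 1006 counts in replicate 1 and 1628, 1663, 1369 and 932 counts in replicate 2. Xist, the RNA of the inactive X chromosome, and its antisense gene Tsix had 2.52 and 3.48 expected counts in replicate 1 and 0 in replicate 2, although the labels call the sex of each sample mixed.

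Alternative subunits and paralogues, many of them embryonic or progenitor forms against adult or neuronal ones, were compared within each library as ratios for 33 gene pairs. In whole tissue such ratios also depend on the mix of cells, which was not measured. The TPM intervals of the 2 genes lay apart in both libraries, in the same direction, for 31 pairs. The NMDA receptor gene Grin2b (chromosome 6, 135713233 to 136173511, minus strand) exceeded Grin2a by 5.70 ± 0.72 on the log2 scale (16.7 ± 7.62 against 0.305 ± 0.00707 TPM). The log2 ratio was 3.10 ± 0.38 for the sodium channel genes Scn3a over Scn8a. Among AMPA receptor genes, Gria2 exceeded Gria1 by 2.11 ± 0.07. Among regulators of the switch from progenitor to neuron the direction varied. The splicing regulator Ptbp2 exceeded Ptbp1 (log2 ratio of Ptbp1 over Ptbp2, -1.47 ± 0.01) and the BAF complex subunit Dpf1 exceeded Phf10 (log2 ratio of Phf10 over Dpf1, -2.89 ± 0.23). Actl6b exceeded Actl6a by less (log2 ratio of Actl6a over Actl6b, -0.40 ± 0.24), and the progenitor subunit gene Ss18 exceeded Ss18l1 (0.55 ± 0.20), but counts not divided by gene length separated neither of these pairs (-0.02 and 0.04). The chromatin remodeller Chd4 exceeded Chd5 (1.91 ± 0.08) and the DNA methyltransferase gene Dnmt3a exceeded Dnmt3b (3.13 ± 0.03). Not separated in both libraries were the chloride transporters Slc12a2 over Slc12a5 (0.01 ± 0.36) and the topoisomerases Top2a over Top2b (0.02 ± 0.18), whose intervals lay apart in opposite directions in replicate 1 (0.15) and replicate 2 (-0.11). When only protein-coding transcripts counted, Slc12a2 exceeded Slc12a5 by 1.08, since such transcripts held 47.6% ± 1.04 of the TPM of Slc12a5, and Top2b exceeded Top2a (-0.51). Protein-coding transcripts also held only 50.3% of the TPM of Gria2, 37.3% of Phf10 and 24.2% of Chd5. The size of those ratios therefore depends on the transcripts counted.

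**Figure D2:**
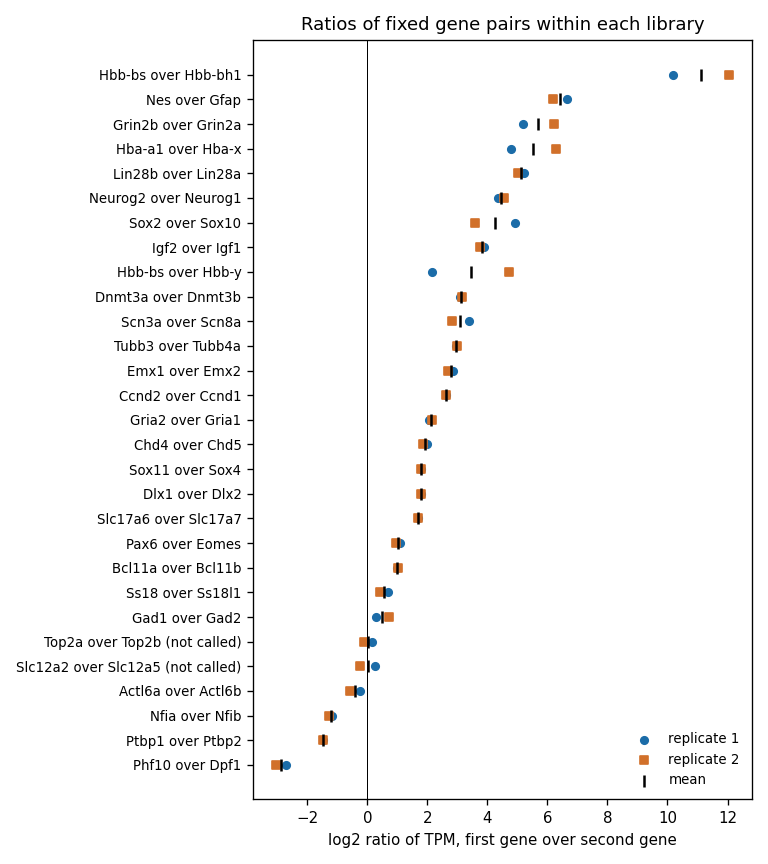
Each row gives the log2 ratio of TPM of the first gene over the second in replicate 1 (circles) and replicate 2 (squares), with the mean as a bar. Lin28a, with fewer than 3 counts in each library, was set to the level of 3 counts, not every pair is drawn, and the largest gap between the libraries is that of Hbb-bs over Hbb-y, 2.16 and 4.73.

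Ratios between regional and lineage factors had a smaller spread between the embryos than those of globins. Log2 ratios were 2.78 ± 0.11 for Emx1 over Emx2, 4.45 ± 0.13 for Neurog2 over Neurog1, 1.02 ± 0.09 for Pax6 over Eomes, 1.79 ± 0.01 for Sox11 over Sox4 and 2.97 ± 0.00 for Tubb3 over Tubb4a. Nfib exceeded Nfia (log2 ratio of Nfia over Nfib, -1.23 ± 0.05), the cyclin gene Ccnd2 exceeded Ccnd1 (2.62 ± 0.01), and the vesicular glutamate transporter gene Slc17a6 exceeded Slc17a7 (1.70 ± 0.01). Nes exceeded Gfap, the filament of mature astrocytes, by 6.42 ± 0.31, Sox2 exceeded Sox10 by 4.25 ± 0.95, and Igf2 exceeded Igf1 by 3.83 ± 0.10. Lin28b had 175 and 153 counts, against 2 counts of Lin28a in each library. Dlx1 exceeded Dlx2 by 1.78 ± 0.00, but with protein-coding transcripts only the direction was opposite (-1.16), because transcripts with a retained intron held 87.6% ± 0.784 of the TPM of Dlx1, a locus that the antisense gene Dlx1as overlaps. Bcl11a exceeded Bcl11b by 1.00 ± 0.04, a direction that counts not divided by length turned (-0.16). Gad1 exceeded Gad2 (0.50 ± 0.30), a call that was lost with protein-coding transcripts only (0.04) and with counts not divided by length (0.16). Adult globins exceeded embryonic ones, with log2 ratios of 3.45 ± 1.82 for Hbb-bs over Hbb-y, 11.12 ± 1.32 for Hbb-bs over Hbb-bh1 and 5.53 ± 1.07 for Hba-a1 over Hba-x. Protein-coding transcripts held only 46.5% of the TPM of Hbb-bs and 29.8% of Hba-a1, so the size of these ratios depends on the transcripts counted.

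Non-coding, mitochondrial and spike-in RNA made up the rest of the libraries. Nuclear protein-coding genes held 81.4% and 83.4% of TPM in replicates 1 and 2, which was 91.64% (95% Wilson interval, 91.63 to 91.65) and 92.92% (92.91 to 92.93) of counts. The intervals cover counting error only, since reads that come from amplification are not independent molecules. Mitochondrial genes held 3.93% and 2.96% of TPM, long non-coding RNA 2.39% and 2.23%, and pseudogenes 5.27% and 4.24%. Small non-coding RNA held 2.73% and 1.84% of TPM but 0.274% and 0.157% of counts. The signal recognition particle RNA genes Rn7s1 and Rn7s2, near-identical copies, stood at 7794 ± 2660 and 7795 ± 2663 TPM, the polymerase III transcript Rn7sk at 542 ± 240 TPM, and the RNase P RNA Rpph1 at 111 ± 11.4 TPM. The 6 RNAs of this list had a median of 327 ± 126 TPM (100th percentile). Replication-dependent histone genes, a class whose messages mostly lack a poly(A) tail, had a median of 3.87 ± 1.10 TPM over 68 genes taken by symbol, against 590 ± 125 TPM for 7 polyadenylated variants and 88.5 ± 11.2 TPM for 5 S-phase genes. The sums of these sets were 3746 ± 1042, 9276 ± 460 and 518 ± 38.4 TPM in the same order. By sum the histone genes thus stood above the S-phase genes, so the low median does not mean that their messages were absent. Whether the message of each of the 68 lacks a poly(A) tail was not tested, and Hist1h2ap alone made up 2214 of the 3746 TPM. The sum therefore does not show that messages without a tail were captured. The 68 include 3 pseudogenes, genes without a read such as Hist1h1t, and H1f0, which fell in both histone sets. Without H1f0 the first median was 3.66 ± 0.827 TPM, and without H1f0 and the pseudogenes it was 4.11 ± 1.44 TPM over 64 genes. Of the 68 genes, 18 had a TPM of 10 or more in both libraries, led by Hist1h2ap at 2214 ± 668 TPM, and reads shared among these near-identical genes make the single values uncertain. Spike-ins took 1.87% (1.86 to 1.87) and 2.19% (2.18 to 2.20) of counts. Of the 96 spike-ins, 75 had a count in both libraries, and for the 60 with 10 or more counts in both the median log2 count ratio of replicate 2 over replicate 1 was -0.07, against -0.28 for the summed counts of all genes.

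Transcript shares were compared for 20 genes with well-known alternative transcripts. The most abundant transcript was the same in both libraries for 19 of them, and it held more than 50% of the gene's TPM for 13. With posterior mean TPM these counts were 19 and 11, and with protein-coding transcripts only they were 18 and 15. With protein-coding transcripts only, 13 of 19 shares moved by more than the spread of the 2 libraries. Ptbp2 has 1 listed transcript and so had no choice. Pkm and Cdc42 have 2 each, so their leading transcript holds 50% or more by arithmetic. Gnas-208 held 83.4% ± 1.25 of Gnas, Ncam1-204 78.6% ± 0.446 of Ncam1, Snap25-201 78.5% ± 0.450 of Snap25, Nfib-202 73.1% ± 3.56 of Nfib and Dlg4-201 69.5% ± 5.77 of Dlg4. Dcx-201 held 63.9% ± 8.27, Pkm-201 59.3% ± 5.36, Clta-204 58.2% ± 0.418, Kif1b-203 57.4% ± 3.08, the leading Cdc42 transcript (ENSMUST00000051477.8) 55.8% ± 1.80, Numb-204 55.7% ± 3.94 and Map2-201 52.8% ± 2.98. Lower shares were those of Src-202 at 47.3% ± 1.06, the leading Fgfr1 transcript (ENSMUST00000117179.4) at 42.2% ± 4.95, Dab1-203 at 41.3% ± 0.825, Pax6-207 at 29.4% ± 0.388 and Meg3-205 at 27.5% ± 5.54. Mapt was the exception between the libraries, where Mapt-204 led in replicate 1 with 43.0% and Mapt-205 in replicate 2 with 43.7%. The lead in replicate 1 was narrow, as Mapt-205 held 41.5% there.

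The 2 embryos differed in few genes. Of 11010 genes with a mean TPM of 5 or more, 53 (0.481%) differed by 2-fold or more with TPM intervals apart, 34 higher in replicate 2 and 19 higher in replicate 1. The largest differences toward replicate 1 were in short RNAs, namely the annotated snRNA genes Gm24407 (29.1 against 1.35 TPM) and Gm24265 (32.3 against 5.41 TPM), Snora68 (20.5 against 1.77 TPM), Rmrp, the RNA of RNase MRP (102 against 18.7 TPM), the scaRNA gene Gm26083 and Rn7s6. The values of Gm24407, Snora68 and Gm24265 are unreliable, since they rest on 28, 15 and 31 counts against 1, 1 and 4 at effective lengths of 32 to 42 nt. The embryonic beta-like globin Hbb-y (chromosome 7, 103851749 to 103853216, minus strand) stood at 529 and 123 TPM, and 3 histone genes, Hist1h2ai, Hist1h4n and Hist1h2ak, completed the first 10. In all, 5 of the 19 were replication-dependent histone genes and 6 were small non-coding RNAs, and their median effective length was 331 nt, against 2310 nt for the genes compared. Toward replicate 2 the largest differences were those of Gm37676 (0.700 against 12.9 TPM) and of Xlr3b, a member of an X-linked multigene family (8.84 against 37.2 TPM), followed by Gm26833, an unnamed gene (ENSMUSG00000104447.1), Gm5812, Nav2, a second unnamed gene (ENSMUSG00000086568.2), Gm26909, Sidt1 and Dlgap2. Others among the 34 were Col1a1 (17.1 against 35.5 TPM) and Malat1 (1163 against 2387 TPM, at an effective length of 486 nt in the files). Gm37376, which lies antisense inside Malat1, differed the same way (471 against 1038 TPM), and reads of the 2 strands may not have been told apart.

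**Figure D3:**
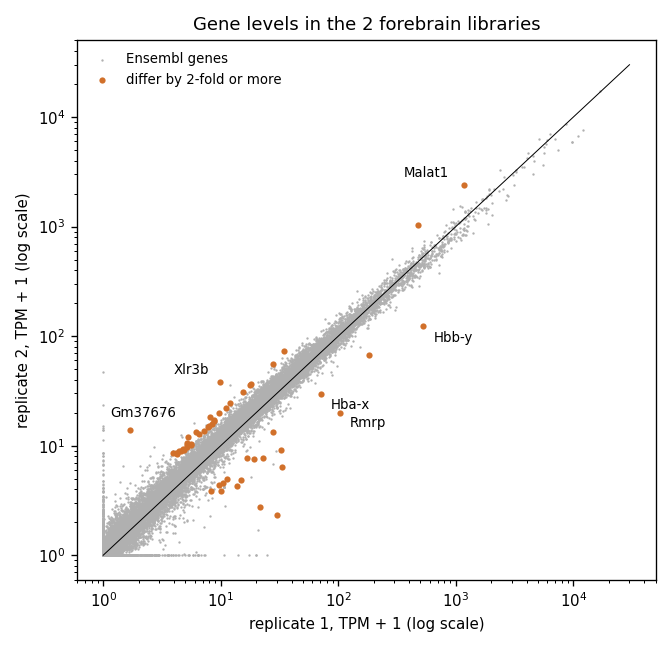
Each point is an Ensembl gene, with TPM + 1 in replicate 1 on the horizontal and in replicate 2 on the vertical axis, both on log scales, and the line marks equal values. Orange points are the 53 genes that differed by 2-fold or more, such as Hbb-y (529 against 123 TPM) and Xlr3b (8.84 against 37.2 TPM).

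Over 14758 genes with a mean TPM of 1 or more, the SD of the log2 ratio of the libraries was 0.36, Pearson's r across genes 0.985 and Spearman's rho 0.986, where genes are not independent replicates. The median log2 ratio was 0.14 toward replicate 2 in TPM and -0.02 after TMM scaling of counts. With TPM scaled by TMM factors, 44 genes differed, 9 higher in replicate 2 and 35 higher in replicate 1, and 28 of the 53 remained. Col1a1 and Malat1 were among those lost, as their log2 ratios of 1.05 and 1.04 became 0.87 and 0.85, just under 2-fold. The biological coefficient of variation was 0.13 over 16155 genes. The chi-square of the counts was 28.2 times its 18195 degrees of freedom, so neither table was a copy of the other, while library preparation adds noise beyond counting as well. With 1 library per embryo these differences compare the libraries and have no replicate check.

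Lists of neuronal genes and of genes of dividing cells ranked in opposite directions between the 2 libraries. Of 32 lists, 7 ranked higher and 6 ranked lower in replicate 2 than random lists matched on expression, and 4 and 6 of these had a Benjamini-Hochberg adjusted rank probability under 0.05, which the striatal, pericyte and oligodendrocyte lineage lists did not have. TMM normalization of counts moved the median of all genes by over 0.1, so the list medians shift with it, and their ranks among random lists are the measure that compares. Upper-layer cortical genes were higher in replicate 2 in 7 of 7 members, with a median log2 ratio of 0.77, where random lists gave 0.16 (100th percentile), as in Mef2c (35.7 against 61.8 TPM) and Cux2 (13.8 against 25.5 TPM). General neuronal genes had a median of 0.38 against 0.05 for random lists (100th percentile), 11 of 12 higher in replicate 2, as in Mapt (285 against 502 TPM). Striatal genes had a median of 0.37 (99.1th percentile), meningeal genes 0.39 (99.4th percentile), pericyte genes 0.43 (98.9th percentile), oligodendrocyte lineage genes 0.40 (98.4th percentile) and nuclear long non-coding RNAs 0.66 (100th percentile). Cell cycle genes were lower in replicate 2 in 11 of 12 members, with a median of -0.23 where random lists gave 0.08 (0.01th percentile), as in Cdk1 (251 against 177 TPM). Radial glia genes had a median of -0.12 (0.110th percentile), with 8 of 12 lower, and intermediate progenitor genes one of -0.17 (0.0800th percentile), with 9 of 9 lower. With TMM-normalized counts the medians were 0.54 for upper-layer, 0.17 for neuronal, 0.18 for striatal, -0.26 for radial glia, -0.35 for intermediate progenitor and -0.38 for cell cycle genes, and on residuals of the fit on length, GC content and expression 0.47, 0.25, 0.28, -0.29, -0.25 and -0.36 in the same order. The residual medians of the pericyte and oligodendrocyte lineage lists were 0.19 and 0.22. The small polymerase III and RNase RNAs had a median of -0.71 (0th percentile), which was -0.44 on residuals of 5 of the 6 genes. The pituitary and eye lists were also lower in replicate 2 (medians of -0.38 and -0.18), on 3 and 6 genes of which only Pomc exceeded 1 TPM in both libraries. The dorsal, deep-layer and ventral lists lay inside the range of random lists, with medians of 0.10, 0.26 and 0.18. Red blood cell genes did as well (0.20, 94.8th percentile), with Hbb-bs (2370 against 3273 TPM) higher in replicate 2 and the embryonic globins Hbb-y and Hba-x (69.7 against 28.4 TPM) lower. After a fit on transcript length, GC content and expression this list ranked higher in replicate 2 (100th percentile) and the pericyte list no longer did (95.8th percentile). With TMM-normalized counts the astrocyte list (98.6th percentile) and the immediate early list (97.9th percentile) also ranked higher, and the polyadenylated histone variants lower (0.17th percentile). Some other alternatives gave these calls too and others did not. A pseudocount of 0.1 called the astrocyte (98.2th percentile) and immediate early (98.3th percentile) lists higher. Matching on effective length as well called the histone variants lower (0.895th percentile) and red blood cell genes higher (99.8th percentile).

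**Figure D4:**
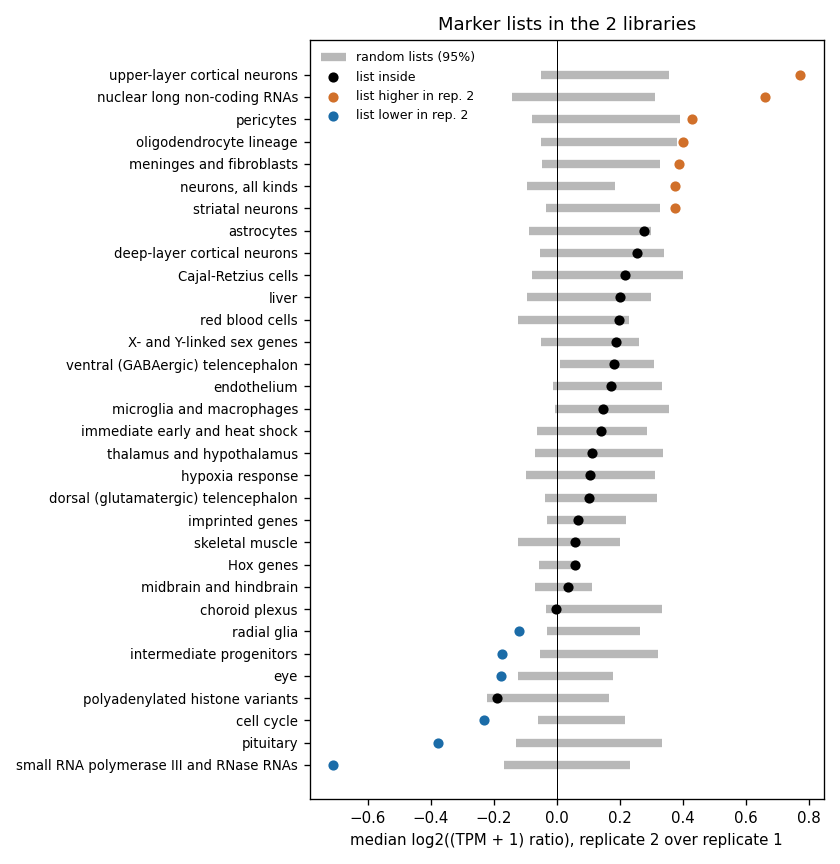
Dots are each list's median log2 ratio of TPM + 1, replicate 2 over replicate 1, and grey bars the central 95% of 10000 random lists matched on expression. Upper-layer genes lie farthest to the right (0.77) and small polymerase III and RNase RNAs farthest to the left (-0.71).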

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

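The tests on blood, on dorsal tissue and on sex below were chosen after the result was seen. Entries of 2 kinds that were in no gene list or pair held counts. Ensembl genes with no name in the later annotation, 884 in number, entered only the comparisons over all genes and classes and held 52643 counts in replicate 1 and 46827 in replicate 2. Entries with numeric IDs held 6 counts in each library in sum, over 26248 entries, more than the 3 counts that a count of 0 allows only as a sum, since none of them exceeded 3 counts by itself.

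Neuronal genes were higher, and cell cycle genes and embryonic globins lower, in replicate 2 than in replicate 1. A trend with transcript length, GC content or expression level is argued against as the whole cause, since on residuals of a fit on these properties (99.4% of genes covered) the neuronal list stayed at the 100th percentile, with a median of 0.25 against 0.38 before. A different amount of blood does not account for the globins, because Hbb-y over the sum of Hbb-bs and Hbb-bt differed 5.46-fold between the libraries (95% counting interval, 5.13 to 5.81), while blood would move these genes alike. More dorsal tissue in one dissection is argued against only as the whole cause, since it would move genes of dorsal and ventral origin apart. The striatal (99.1th percentile) and upper-layer (100th percentile) lists instead both ranked higher in replicate 2. The striatal list did not, however, have an adjusted rank probability under 0.05. The medians of the dorsal and ventral lists differed by -0.0790 (bootstrap interval over genes, -0.283 to 0.212). This interval rests on 9 and 15 genes, and the upper-layer list moved more than the striatal list (medians of 0.77 and 0.37). A regional shift within the interval, beside another cause, is therefore not excluded. Other differences in dissection are not excluded. The meningeal list ranked higher in replicate 2 (99.4th percentile, and 99.8th on residuals), and unequal meningeal tissue was not tested as a cause. A later developmental stage of the replicate 2 embryo is a candidate explanation that stays open. Of 7 genes that fall with embryonic age, 5 could be fitted. Their median residual lay at the 1.08th percentile of random lists, although their unadjusted log2 ratios lay at the 7.08th. The Benjamini-Hochberg adjusted rank probabilities were 0.055 and 0.248, neither under 0.05. Cell cycle and radial glia genes were lower too, so these 5 genes cannot tell a later stage from a smaller share of progenitors. No stage beyond the shared age label was given.

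Both libraries had Y-linked counts, 5996 and 5592 over 4 genes, while Xist and Tsix summed to at most 6 counts, in replicate 1. Tissue of both sexes in each sample is argued against by this value, because female tissue would bring Xist, an abundant RNA there. No biological explanation was tested, and a label that describes the collection and not the single embryo stays open.

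Unprocessed pseudogenes were among the most abundant genes, led by Gm28437 (chromosome 1, 24613189 to 24613971, minus strand) at 8828 ± 3026 TPM and Gm10925 at 3570 ± 117 TPM. All 6 such genes with a mean TPM of 100 or more lie side by side on chromosome 1, and 100% of their summed TPM was in genes for which most 50-base windows occur exactly in a mitochondrial transcript. Reads shared with mitochondrial transcripts are consistent with this, so the share of mitochondrial RNA may be understated and that of pseudogenes overstated. No biological explanation was tested.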

How the results depend on the processing

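The residual and length-matched list ranks and the histone medians without H1f0 or pseudogenes were added after seeing the data. Counts of genes detected (10636 to 18849), of pairs called (29 to 32) and of lists apart between the embryos stayed within 1.5 times the reported values under all alternatives run, as did lists called high (6 to 10). Lists called low numbered 3 with posterior means, 8 with a background of genes at 0.1 TPM or more, and 1 to 2 with each library alone. Genes that differ numbered 190 from a mean TPM of 1, 618 at 1.5-fold and 7 at 4-fold, by construction of these thresholds. With exact Poisson intervals of the expected counts in place of the deposited intervals, 73 genes differed. The SD of log2 ratios was 0.57 with a pseudocount of 0.1, 0.25 without a filter, 0.28 from a mean TPM of 10, 0.27 with TMM-normalized CPM, 0.28 with posterior means and 0.28 over protein-coding nuclear genes. The coefficient of variation was 0.134 with library totals and 0.136 without a filter. As a share of counts and not of TPM, nuclear protein-coding genes held 92.3%, long non-coding RNA 2.16%, mitochondrial genes 1.71%, pseudogenes 1.46%, small non-coding RNA 0.215%, spike-ins 2.03%, genes outside the later annotation 0.155%, entries with numeric IDs 1.88e-05% and other types 0.000545%, as TPM divide by length. With posterior mean TPM, 80.8% was nuclear protein-coding, 3.93% small non-coding, 0.205% outside the later annotation, 0.0132% in numeric IDs and 0.00949% in other types. Spike-ins held 4.65% of TPM, with a median log2 ratio of 0.31 in TPM. The sum of histone genes was 3746 TPM. Of the pair ratios, 2 turned, Dlx1 over Dlx2 with protein-coding transcripts only (-1.16) and Bcl11a over Bcl11b with counts not divided by length (-0.16), both through the lengths or transcripts counted. Of the remaining pair values, 6 lost and 6 gained the call, and for 217 the call or the lack of one was unchanged, while pseudocounts and posterior means leave these calls alone by construction. List ranks between the embryos lost the call once, for pericytes on residuals (95.8th percentile), gained it in 11 cases and were unchanged, called or not, in 170. These numbers leave out lists with too few members to score. The pituitary and eye lists, called lower in replicate 2, had no score on residuals or with members limited to a mean TPM of 1 or more. List levels lost the call in 3 cases, gained it in 11 and were unchanged, called or not, in 178. The 3 losses and 7 of the gains came with the background of genes at 0.1 TPM or more. That filter lowers ranks by construction, since it was not applied to the list members. Where no construction is named, the cause was not tested. Results between the embryos have no value with 1 library left out. No paired analysis was possible because there is 1 group. At this depth, a count of 0 allows levels up to 0.131 and 0.170 TPM in replicates 1 and 2 for a transcript with an effective length of 1 kb.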

Other observations

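Gene families not described above were taken by symbol after the data were seen. Of 19 Sox factors, 16 had a TPM of 1 or more in both libraries, and Sox11 alone held 63.2% of the family's TPM. Among Wnt ligands 8 of 19 were detected, led by Wnt7b at 61.9 ± 6.84 TPM (SD, n = 2) and Wnt7a at 16.4 ± 0.170 TPM, and among 10 Frizzled receptors 9, led by Fzd3 at 41.5 ± 11.7 TPM. The Notch ligand Dll1 stood at 22.5 ± 2.71 TPM, Dll3 at 12.8 ± 1.02 TPM and Jag1 at 6.47 ± 1.48 TPM. Axon guidance genes were broadly present. All 8 ephrins, 11 of 14 Eph receptors, 17 of 20 semaphorins and 8 of 9 plexins were detected, with Epha4 at 72.7 ± 3.91, Epha5 at 59.9 ± 14.7, Epha3 at 54.4 ± 1.44, Plxnb2 at 79.6 ± 2.84 and Plxna2 at 51.0 ± 6.99 TPM. Nuclear factor I genes, regulators of glial and neuronal differentiation, were led by Nfix at 232 ± 52.9 TPM.

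Receptors for transmitters were already varied at this age. Of 19 GABA-A receptor subunit genes, 13 were detected, among them Gabra5 at 21.4 ± 3.46 TPM. Of 18 ionotropic glutamate receptor subunit genes, 13 were detected, and Gria2 held 44.4% of their TPM. The sodium channel gene Scn3a held 58.6% of the TPM of 10 alpha subunits. Of 21 gamma-protocadherin genes, which encode adhesion molecules with shared exons, 20 were detected, led by Pcdhgc4 at 51.9 ± 0.658 TPM and Pcdhgc3 at 29.7 ± 8.19 TPM. Tubulins were dominated by Tuba1a, with 70.1% of their TPM.

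Some values stood out without a test. Gm42418, annotated as a lincRNA, had 12151 and 7582 TPM in replicates 1 and 2. It held 481617 of the 829375 counts of long non-coding RNA in replicate 1 and 231372 of 574015 in replicate 2. This 1 gene thus held most of the long non-coding RNA counts in replicate 1 and a large part, but not most, in replicate 2. The origin of its reads was not tested. Among the genes that fall with embryonic age, Hmga2 had 181 and 81 counts, the largest ratio of the 5 that could be fitted. The annotated miRNA gene Gm22133 reached 5661 and 4734 TPM from 1295 and 834 counts, on a very short effective length that makes these TPM unreliable. It lies inside the abundant gene Ftl1 on the same strand, so its reads may be those of Ftl1.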
